A study of Arabidopsis thaliana with 34 samples.

How the data were processed

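Transcripts were measured on 34 Affymetrix ATH1 arrays, 1 array per RNA sample, from leaves of 3 Arabidopsis thaliana accessions in 4 conditions. Per the labels' protocols, plants were grown at a day length of 16 h and 20 °C by day and 18 °C by night for 42 days, and then kept at 4 °C for 14 days in weaker light (90 µmol m-2 s-1). Sub-zero leaves were detached, placed in tubes with water and kept in an oil bath at -3 °C in darkness, where no ice formed. Per the labels' protocols, RNA was extracted with the RNeasy Mini Kit and amplified and biotin-labelled with the MessageAmp II kit. The values are log2 intensities that the authors made with RMA (background correction, quantile normalization and summary per probe set), per the submitters' processing notes, with the version not given in the sources used here. That the deposited scale is log2 was taken from the range of the values. Arrays were grouped by accession and condition from their titles. For the third cold acclimated replicates another label gives the replicate number as 2, and the title was followed. The labels describe 3 independent biological replicates, and Col at 8 h and Col at 3 d had 2 arrays each. The number of arrays limits the precision.

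The table held 22810 probe sets. The 64 control probe sets were left out of the tests, and the other 22746 were tested without a filter. Gene names came from a platform annotation that may be old, and symbols were updated by gene number through a RefSeq table of assembly TAIR10.1, used for names only, with no coordinates. Of the tested probe sets 13513 had 1 gene, giving 13355 genes, 503 had several and 8730 were unnamed here. Of the probe sets with 1 gene, 13436 were matched to the RefSeq table and 77 kept the name of the annotation. Only probe sets with 1 gene are named in the text.

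A linear model with 1 mean for each of the 12 groups was fitted to all 34 arrays with limma 3.58.1 (lmFit, contrasts and eBayes with default settings, in R 4.3.3), which left 22 residual degrees of freedom. All groups entered 1 fit because 2 groups had 2 arrays. The contrasts were each time against cold acclimated leaves, averaged over accessions with equal weight and within each accession, then successive times averaged over accessions, and the accessions against each other when cold acclimated. Whether the change from the cold acclimated state was equal in the 3 accessions was tested with limma's moderated F test. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, two-sided. Errors of log2 changes are standard errors from the fit with the moderated variance. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and plots.

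Gene lists were tested with limma's camera at its preset correlation of 0.01, and again with the correlation estimated from the data, using the probe set with the highest mean for each gene. Adjustment was over the lists tested within a contrast. Of 24 lists with 519 entries, 88 entries had a probe set named here, 10 lists had the 5 measured genes needed for the test, and 5 lists had none. A gene is called measured where it has a probe set named here. Other list entries may lie among the unnamed probe sets. A list of cytosolic ribosomal proteins was not possible without annotation text and was not analysed here. The groups, contrasts, tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule took, for each averaged time contrast, the 8 highest and 8 lowest called changes with the same sign in the 3 accessions. It took the 6 highest and 6 lowest for each accession contrast, the 6 smallest p for each interaction, and up to 4 called members with the largest change for each list and contrast (the member with the largest change where none was called). It also named CBF1, CBF2, CBF3 and COR15A. Genes chosen after their values were seen are said to be so. Gene families by symbol stem and the organelle-encoded genes were formed once the annotation had been seen and before their tests were run.

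The fits were repeated in other ways, laid down beforehand, by leaving out dim probe sets (those whose largest group mean lay below the 40th percentile of all values, 5.32 log2, which kept 14993), quantile normalization, centring each array on its median, leaving out probe sets with the suffixes _s_at and _x_at (which kept 21685), array weights, the replicate number as a block, accession and replicate as a random block, fitting only the arrays compared, eBayes with trend and robust settings, leaving out each array, and the mean of a gene's probe sets for lists. After seeing the data, 4 were added: the set of arrays split by the bioC control level as a block, each of the 2 sets alone, and leaving out 2 doubted Te arrays. The 2 sets were split at 7.81 log2, in the widest gap of the bioC means.

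Arrays with the same replicate number were checked for shared deviations from their group means, with a correlation over 0.1 in every one of at least 3 pairs taken as pairing. All 25 pairs of a sub-zero array with the cold acclimated array of its accession and number lay between 0.16 and 0.60. Rsch and Col arrays of equal number correlated at 0.26 to 0.61 when cold acclimated. Arrays at 8 h and 1 d also paired in Rsch (0.32 to 0.59) and Te (0.26 to 0.44), and those at 1 d and 3 d in Rsch (0.45 to 0.55). Te did not pair with Col (-0.08 to 0.19) or with Rsch (0.05 to 0.27) when cold acclimated, nor at 1 d with 3 d within Te (-0.24 to 0.01). Col at 8 h and 3 d had 2 pairs, too few for this check. The main fit, with 1 mean per group, left the pairing out, so its standard errors and p-values ignore it. The replicate number as a block is an effect shared by all accessions. Only the random block follows accession and number together.

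The fits were tested on simulated data with the spread of these arrays. At 8 h against cold acclimated leaves, averaged over accessions, 70.1%, 97% and 100% of changes of 0.5, 1 and 2 log2 were recovered among 22746 probe sets, with 8 false calls. Within Te at 8 h 19.4%, 80.6% and 95.5% were recovered, and within Col at 8 h, with 2 arrays, 13.4%, 76.1% and 93.9%. Between 3 d and 1 d 53.7%, 89.6% and 100% were recovered, and between Te and Col 26.9%, 79.1% and 98.5%. The interaction test at 3 d recovered 3%, 46.3% and 93.9%. For the 3 d contrast over 13355 genes, 20 of 20 lists shifted by 1 log2 were called with either correlation, and 0 of the other simulated lists. Simulated genes and arrays varied independently, whereas the correlation estimated for a real list reached 0.726 (flavonoid genes). The simulation therefore cannot tell how often lists of genes that vary together are called falsely.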

Results

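Leaf transcripts were measured in 3 naturally occurring accessions of Arabidopsis thaliana, Columbia-0 (Col), Rschew (Rsch) and Tenela (Te), to follow how expression changes with time during sub-zero acclimation. Plants were grown for 42 days and cold acclimated for 14 days at 4 °C, and leaves detached from them were then held supercooled at -3 °C, with samples taken after 8 h, after 1 d and after 3 d. Each of the 12 combinations of accession and condition had 3 arrays, except Col at 8 h and Col at 3 d with 2 each. This made 34 arrays, each from an RNA pool of 3 leaves of 3 plants. Values are log2 intensities of 22746 probe sets on the ATH1 array, whose probes follow the Columbia-0 sequence. The arrays had medians of 5.97 to 6.22, and their number limits the precision. The sub-zero leaves were detached and in darkness, while the cold acclimated leaves came from intact plants in a 16-h day, so a change against the latter belongs to the whole treatment and not to temperature alone.

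**Figure D1:**
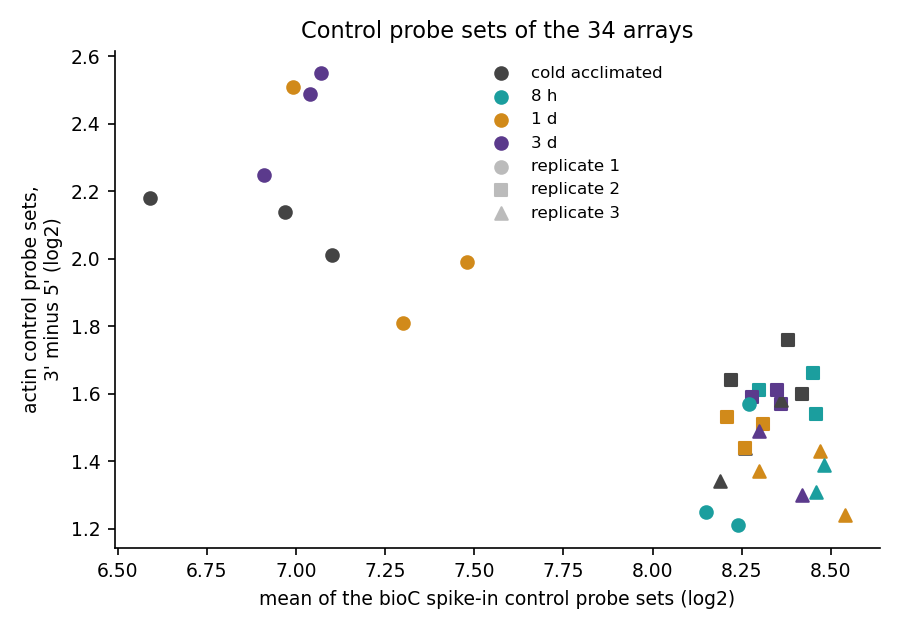
Mean log2 level of the bioC spike-in probe sets (x axis) against the log2 difference between the 3' and 5' actin probe sets (y axis), with 1 point for each of the 34 arrays, coloured by condition and shaped by replicate number. The bioC level lies between 6.59 and 7.48 on 9 arrays and between 8.15 and 8.54 on the other 25.

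The bioC control probe sets split the arrays into 2 sets. BioC, a transcript added at hybridization, had a mean log2 level of 7.05 on 9 arrays and of 8.34 on 25. The 9 arrays were replicate 1 of the cold acclimated, 1 d and 3 d groups of each accession, and the 8 h groups lay in the larger set. No label gives a hybridization date or batch, so whether the sets are hybridization batches is not known. The actin 3' minus 5' difference, a sign of RNA or labelling quality, averaged 2.21 log2 on the 9 arrays and 1.48 on the 25. By condition it averaged 1.74 ± 0.30 (SD, n = 9) when cold acclimated, 1.44 ± 0.18 (n = 8) at 8 h, 1.65 ± 0.40 (n = 9) at 1 d and 1.86 ± 0.49 (n = 8) at 3 d. Counts with this set as a block and within the larger set are given with each comparison below. The smaller set, with 1 array per group, no 8 h array and 4 residual degrees of freedom, was fitted for 1 d, 3 d and their difference averaged over accessions. Of the 96 gene results called otherwise in these contrasts, 75 were not called in it. Across probe sets the log2 changes of the smaller set correlated with those of the main fit, which includes its arrays. The correlations were 0.93 at 1 d, 0.91 at 3 d and 0.69 for 3 d against 1 d.

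After 8 h at -3 °C, transcripts of cell wall proteins stood among those with the highest increases over cold acclimated leaves. Averaged over the accessions (8 arrays against 9), AT5G62360, of the pectin methylesterase and invertase inhibitor family, rose by 4.51 ± 0.36 log2 (SE; limma adjusted p = 1.93e-08). XTH18, a xyloglucan endotransglucosylase/hydrolase that remodels the wall, rose by 3.65 ± 0.40 (adjusted p = 1.69e-06). AT5G62360 rose in each accession, by 4.68 ± 0.66 in Col, 3.49 ± 0.59 in Rsch and 5.35 ± 0.59 in Te. XTH18 did so too, with 3.56 ± 0.74, 3.69 ± 0.66 and 3.69 ± 0.66. AT4G22470, of the lipid transfer protein family, rose by 3.26 ± 0.38 and AT5G52050, a MATE efflux carrier, by 3.25 ± 0.39. AT3G15440 rose by 3.17 ± 0.30 and AT3G59350, a protein kinase, by 2.79 ± 0.25. WRKY22, a transcription factor of defence signalling, rose by 2.32 ± 0.32, AT4G28140, of the AP2/ERF factors, by 2.69 ± 0.47, and AT3G54000 by 2.77 ± 0.28. Decreases were smaller. AT3G26510 fell with a change of -1.86 ± 0.39, AT4G28240 with -1.78 ± 0.37, AT1G14200 with -1.74 ± 0.32 and AT1G30250 with -1.61 ± 0.18. BRH1, a RING finger gene that responds to brassinosteroid, fell by 1.58 ± 0.31, and AT3G10190, related to calmodulin, fell by 1.56 ± 0.17. In all, 1352 probe sets (5.9% of those tested) passed limma's test, 764 higher and 588 lower, and 325 were at least 2-fold higher against 45 at least 2-fold lower. Centring each array on its median turned the split to 1009 higher and 384 lower. The count was 979 with the spike-in set as a block, 906 of them shared in direction, and 917 within the larger set (no 8 h array lay in the smaller). It was 2245 with the replicate number as a block and 726 without Col 8 h replicate 1.

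Of the gene groups fixed in advance, 4 were called at 8 h, and none kept its call when the correlation between genes was estimated. Of 7 measured genes of the CBF and COR list, which did not include CBF1, CBF2 or CBF3, 3 rose (5 adjusted over the list alone). COR28, a cold gene linked to the clock, rose by 1.85 ± 0.41, the zinc finger gene ZAT10 by 1.00 ± 0.19 and the dehydrin COR47 by 0.65 ± 0.15. COR28 had an adjusted p of 0.0555 without Col 8 h replicate 1, and fitted on the 8 h and cold acclimated arrays alone COR28 and COR47 were not called (0.0704 and 0.0669). COR15A, which protects chloroplast membranes, was already near the top of the scale, between 12.7 and 13.2 log2 on all arrays, and stood at -0.11 ± 0.06 (adjusted p = 0.3). The list shifted up with limma's camera (adjusted p = 0.00145; adjusted p = 0.195 with an estimated correlation). Of 11 cell wall modifying enzymes, 2 rose (2 adjusted over the list alone), XTH18 and XTH19 with 1.65 ± 0.29, and the list shifted up (adjusted p = 0.0135; adjusted p = 0.195 with an estimated correlation). Photosynthesis genes shifted down as a list (adjusted p = 0.00145; adjusted p = 0.257 with an estimated correlation), although 0 of 10 passed limma's test over all genes and 3 fell adjusted over the list alone. Dark and sugar starvation genes also shifted down (adjusted p = 0.00633; adjusted p = 0.163 with an estimated correlation), with 1 of 5 called (3 adjusted over the list alone), MCCB of leucine breakdown at -0.44 ± 0.13. MCCB lost its call with the spike-in set as a block (adjusted p = 0.0928), with median centring (0.0534) and when any 1 of 11 arrays was left out (adjusted p up to 0.141).

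After 1 d the transcripts of AT5G62360 and XTH18 again stood among the highest increases, although neither was called higher at 1 d than at 8 h (limma adjusted p = 0.234 and 0.112). AT5G62360 rose by 5.29 ± 0.34 (SE, 9 arrays against 9; limma adjusted p = 1.56e-10), AT4G22470 by 4.97 ± 0.36 and XTH18 by 4.75 ± 0.38. AT2G38240, which encodes a dioxygenase that inactivates jasmonate, rose by 4.58 ± 0.37 (adjusted p = 4.45e-09), with 3.49 ± 0.65 in Col, 5.01 ± 0.65 in Rsch and 5.25 ± 0.65 in Te. AT3G15440 rose by 4.07 ± 0.29, AT3G43250 by 3.79 ± 0.43, AT1G51820, a leucine-rich repeat receptor kinase, by 3.67 ± 0.25, and AT1G15010 by 3.33 ± 0.51. On the other side, AT4G27657 fell with a change of -2.29 ± 0.31, AT1G72240 with -2.18 ± 0.20 and AT1G30250 with -2.01 ± 0.18. IQD24, of a calmodulin-binding family, fell by 1.90 ± 0.29, and ORA47, an AP2/ERF factor of the jasmonate response, fell by 1.82 ± 0.54. Limma called 5729 probe sets (25.2%), 2214 higher and 3515 lower, of which 682 were at least 2-fold higher and 237 at least 2-fold lower. Median centring turned the split to 4068 higher and 2342 lower, so the direction of small changes depends on the scaling. With the replicate number as a block 7146 were called. The count was 6291 with the spike-in set as a block, 4328 within the larger set and 441 within the smaller.

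Of 7 measured CBF and COR genes, 5 rose at 1 d (5 adjusted over the list alone). COR28 rose by 2.70 ± 0.40, COR27, its relative, by 1.26 ± 0.21, COR47 by 1.06 ± 0.14, COR15B, a chloroplast protectant, by 0.93 ± 0.16 and the dehydrin LTI30 by 0.52 ± 0.11. ZAT10 stood at 0.33 ± 0.18 (adjusted p = 0.183). The list shifted up (camera adjusted p = 0.000152; adjusted p = 0.0803 with an estimated correlation). COR47, COR15B and LTI30 were also the 3 of 7 late embryogenesis abundant genes that rose (3 adjusted over the list alone), and that list shifted up (adjusted p = 0.0382; adjusted p = 0.186 with an estimated correlation). This call was lost with quantile normalization (0.0554), with median centring (0.0733), on the arrays compared alone (0.0853), and without Rsch cold acclimated replicate 2 (0.0555), Rsch 1 d replicate 1 (0.0535) or Te 1 d replicate 3 (0.0533). Of the cell wall enzymes, 6 of 11 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.000783; adjusted p = 0.0803 with an estimated correlation). Among them XTH19 rose by 3.03 ± 0.28, the pectin methylesterase PME41 by 1.86 ± 0.35 and XTH20 by 1.09 ± 0.18, and the expansin EXPA4 fell by 1.03 ± 0.27. XTH33 rose by 1.70 ± 0.49 but was not called within the larger spike-in set (1.16, adjusted p = 0.147).

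Of 10 photosynthesis genes 4 fell at 1 d (6 adjusted over the list alone). Among them LHCB4.2, a minor antenna protein of photosystem II, fell by 1.27 ± 0.36 and RCA, which activates Rubisco, fell by 0.42 ± 0.11. The calls of PRK, the Calvin cycle's phosphoribulokinase, at -0.60 ± 0.22 and of PSBY at -0.51 ± 0.17 were lost when any 1 of 13 and any 1 of 5 arrays was left out (adjusted p up to 0.0994 and 0.0659), that of PRK also with median centring (0.0764) and that of PSBY on the arrays compared alone (0.051). The list shifted down (camera adjusted p = 0.00774; adjusted p = 0.298 with an estimated correlation). Of 6 flavonoid genes 2 fell (2 adjusted over the list alone). UGT75C1, which glucosylates anthocyanin, fell by 1.60 ± 0.39, and UGT78D1, which attaches rhamnose to flavonols, fell by 1.32 ± 0.16. The flavonoid list shifted down (camera adjusted p = 0.00812; adjusted p = 0.298 with an estimated correlation), with an adjusted p of 0.0549 within the larger spike-in set. The dark and sugar starvation list also shifted down (adjusted p = 0.00812; adjusted p = 0.0803 with an estimated correlation). The 3 of its 5 members that fell (5 adjusted over the list alone) were MCCB at -0.64 ± 0.12, MCCA at -0.48 ± 0.13 and IVD at -0.39 ± 0.11, each an enzyme of leucine breakdown that is known to rise in carbon-starved leaves.

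**Figure D2:**
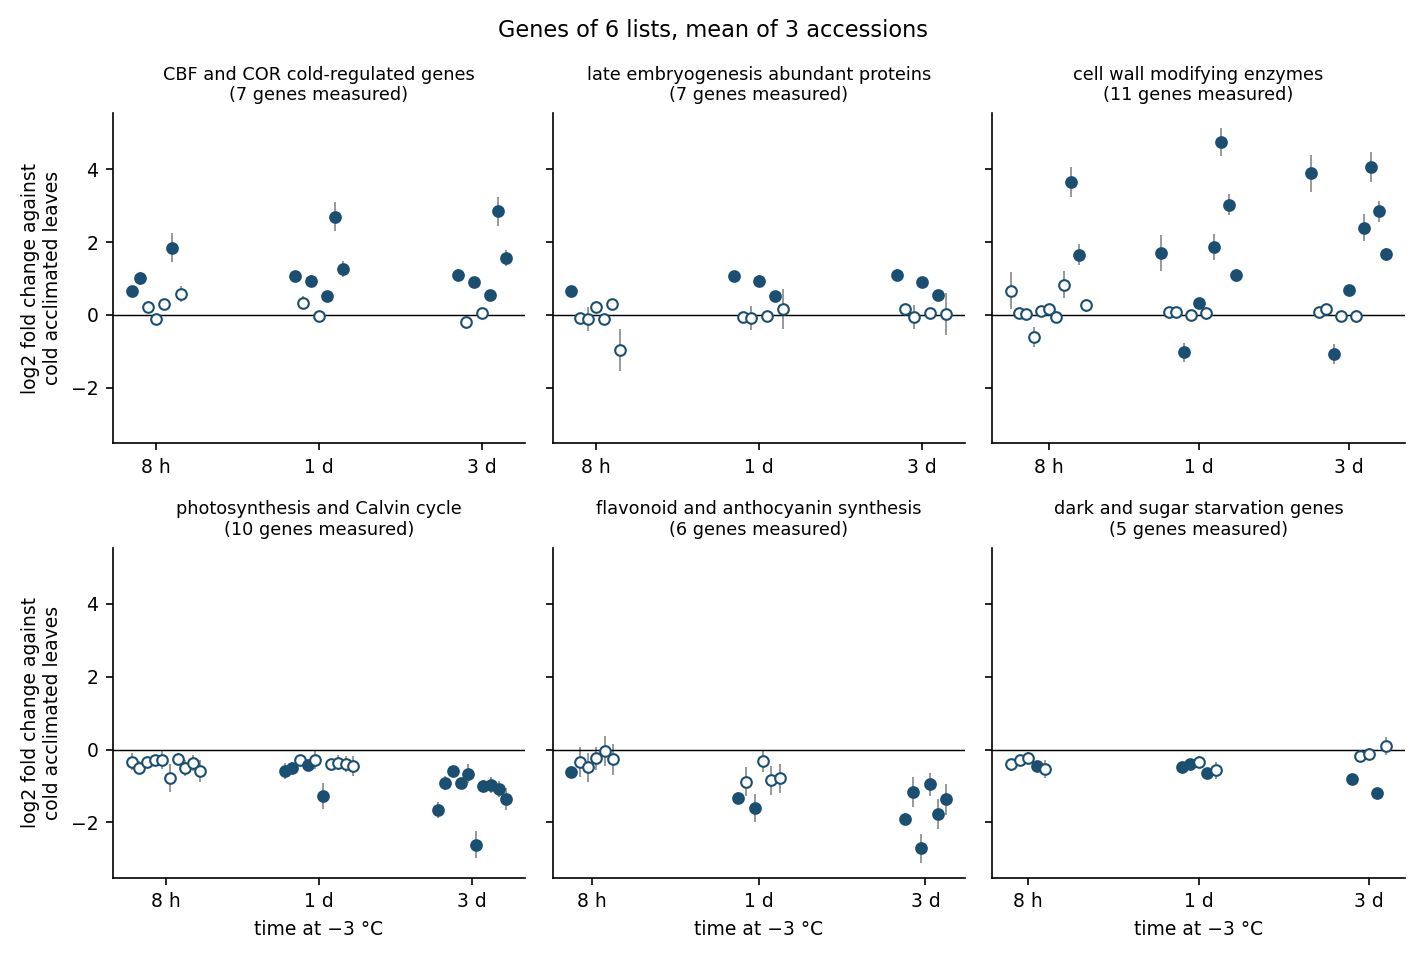
Log2 fold change against cold acclimated leaves, averaged over the 3 accessions (y axis), at 8 h, 1 d and 3 d (x axis) for the members of 6 gene lists; bars are SE and filled points passed the test over all probe sets. All 10 measured photosynthesis genes and all 6 measured flavonoid genes lay below 0 and were called at 3 d. Of the 7 measured genes of the CBF and COR list, without CBF1, CBF2 and CBF3, 5 lay above 0 and were called then.

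After 3 d all 10 measured photosynthesis genes and all 6 measured flavonoid genes stood below the cold acclimated level and were called. Their lists held 58 and 27 entries, most of them not measured here. LHCB4.2 fell by 2.61 ± 0.38 (SE, 8 arrays against 9; limma adjusted p = 8.11e-06). PRK fell by 1.66 ± 0.23, the photosystem I subunit gene PSAN fell by 1.36 ± 0.29 and RCA fell by 0.93 ± 0.11. PRK fell in each accession, with changes of -1.86 ± 0.42 in Col, -1.82 ± 0.37 in Rsch and -1.31 ± 0.37 in Te. All 10 members fell (10 adjusted over the list alone; camera adjusted p = 1.03e-06; adjusted p = 0.14 with an estimated correlation). UGT75C1 fell by 2.71 ± 0.40 and UGT78D1 fell by 1.90 ± 0.17. DFR, the dihydroflavonol reductase of anthocyanin synthesis, fell by 1.76 ± 0.41. All 6 flavonoid genes fell (6 adjusted over the list alone; camera adjusted p = 0.000485; adjusted p = 0.14 with an estimated correlation). UF3GT at -1.37 ± 0.42 was not called within the larger spike-in set (adjusted p = 0.189) or without Col 3 d replicate 1 (0.05). Of the dark and sugar starvation genes, MCCB fell by 1.19 ± 0.13 and MCCA fell by 0.82 ± 0.14 (2 of 5, and 2 adjusted over the list alone). That list's median was -0.18 (camera adjusted p = 0.0438; adjusted p = 0.14 with an estimated correlation). Its call was lost with the spike-in set as a block (0.052), with quantile normalization (0.0735), without dim probe sets (0.155), on the arrays compared alone (0.0532), without Col 3 d replicate 2 (0.076) and without 5 other arrays. The actin difference given above averaged highest at this time.

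Cell wall genes that rose at 3 d were XTH18 by 4.06 ± 0.40, XTH33 by 3.89 ± 0.51, XTH19 by 2.85 ± 0.29, PME41 by 2.39 ± 0.37, XTH20 by 1.66 ± 0.19 and XTH16 by 0.69 ± 0.10, which made 6 of 11 (7 adjusted over the list alone). EXPA4 fell by 1.08 ± 0.28 (1 of 11, and 1 adjusted over the list alone). The list shifted up (camera adjusted p = 0.000485; adjusted p = 0.14 with an estimated correlation). XTH33 rose in each accession, by 4.37 ± 0.96 in Col, 4.60 ± 0.86 in Rsch and 2.71 ± 0.86 in Te. COR28 rose by 2.84 ± 0.41, COR27 by 1.56 ± 0.22, COR47 by 1.1 ± 0.15, COR15B by 0.89 ± 0.16 and LTI30 by 0.56 ± 0.11. These made 5 of 7 CBF and COR genes (5 adjusted over the list alone; camera adjusted p = 0.00108; adjusted p = 0.14 with an estimated correlation). ZAT10 stood at -0.20 ± 0.19 and COR15A at 0.05 ± 0.06. The late embryogenesis abundant list, with 3 of 7 risen (3 adjusted over the list alone), had an adjusted p of 0.0309 (adjusted p = 0.14 with an estimated correlation), 0.0735 with quantile normalization, 0.0559 with median centring and 0.0532 on the arrays compared alone. GIGANTEA (GI) was the only 1 of 22 clock list entries measured here. It rose by 1.29 ± 0.33 at 3 d (1 of 1 adjusted over the list alone) and stood at 0.20 ± 0.33 and 0.47 ± 0.32 at 8 h and 1 d.

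**Figure D3:**
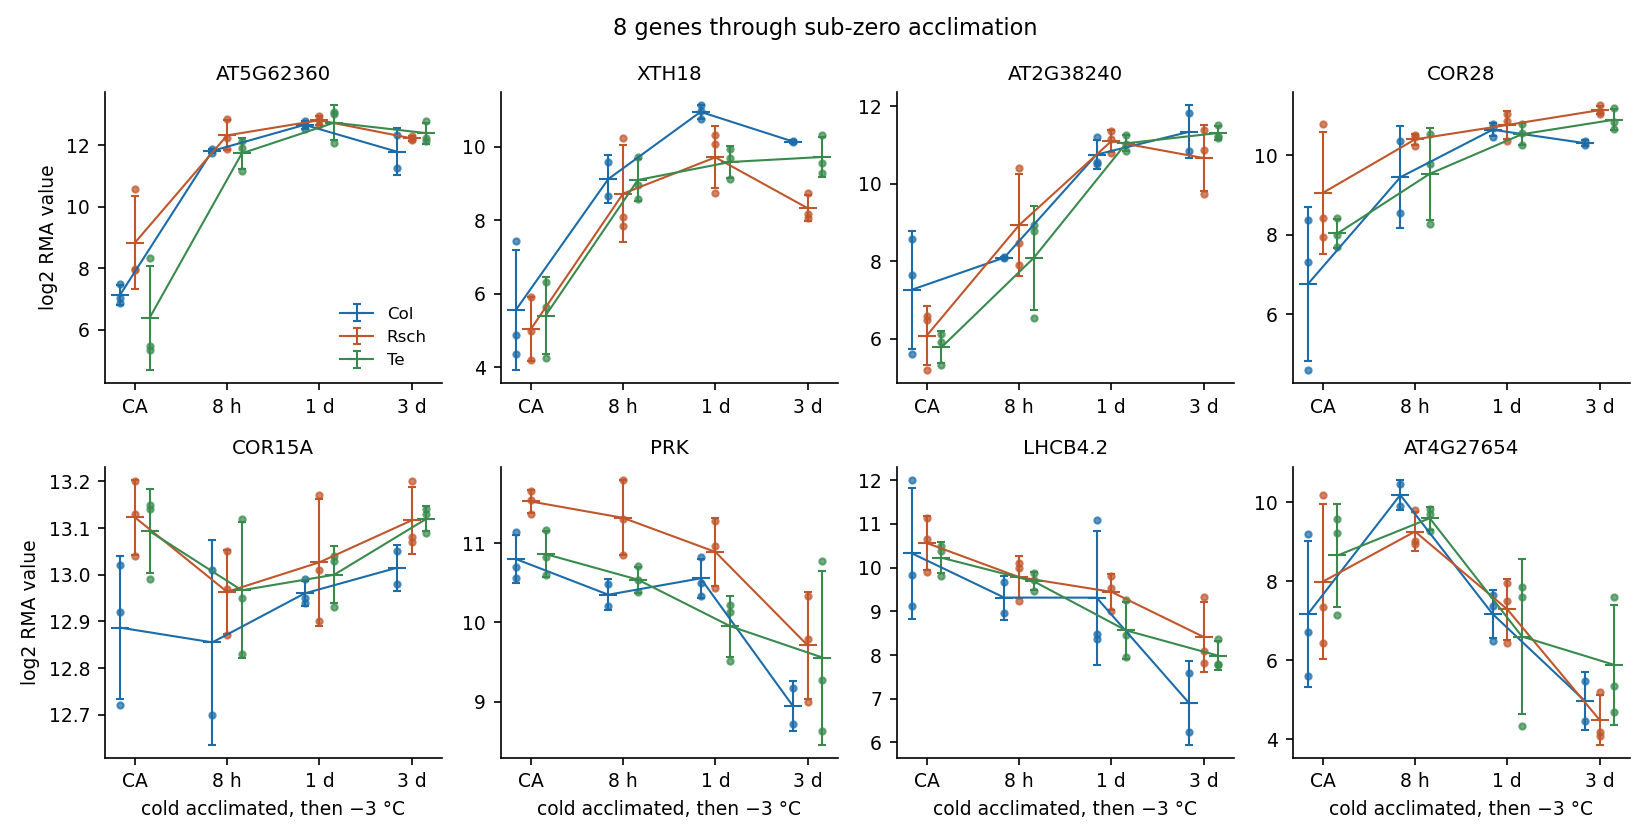
Log2 RMA intensity (y axis, with its own range in each panel) of 8 genes in cold acclimated leaves and at 8 h, 1 d and 3 d (x axis); points are arrays, lines join the group means of each accession, and error bars are SD of 2 or 3 arrays. AT5G62360, XTH18 and AT2G38240 rose, PRK and LHCB4.2 fell at 3 d, and COR15A stayed between 12.7 and 13.2.

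Outside the lists, AT4G22470 rose at 3 d by 5.48 ± 0.38 (limma adjusted p = 3.15e-10), AT2G38240 by 4.72 ± 0.39, AT5G62360 by 4.69 ± 0.36, AT3G15440 by 4.17 ± 0.30, AT1G19530 by 4.02 ± 0.55 and AT1G51820 by 3.88 ± 0.26. AT4G27654 fell with a change of -2.83 ± 0.58, AT5G52760 with -2.70 ± 0.49, AT4G23610 with -2.52 ± 0.38 and AT1G72240 with -2.50 ± 0.21. AT2G42690, of a lipase family, fell by 2.52 ± 0.26, and AT1G54050, a small heat shock protein, fell by 2.49 ± 0.76. The 3 d contrast had 8403 called probe sets (36.9%), 3616 higher and 4787 lower, with 759 at least 2-fold higher and 563 at least 2-fold lower. Median centring gave 7032 higher and 3745 lower, and moved the median of all probe sets by 0.1, from 0.027 to 0.128, so decreases of that order depend on the scaling. With the replicate number as a block 9612 were called. The count was 9054 with the spike-in set as a block, 7618 within the larger set and 755 within the smaller. Without the arrays labelled Te 1 d replicate 1 and Te 3 d replicate 1, for reasons given with their scores, it was 8619 at 3 d and 5713 at 1 d.

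Other lists held few measured genes or were not called. GRX480, a glutaredoxin of the salicylic acid response and the only measured gene of its list, rose by 2.13 ± 0.47 at 8 h and stood at 1.07 ± 0.45 and -0.69 ± 0.47 at 1 d and 3 d (1, 1 and 0 called adjusted over the list alone). PDC2, a pyruvate decarboxylase of the hypoxia list, rose by 0.94 ± 0.20 at 1 d and 0.78 ± 0.21 at 3 d (1 of 2 genes at both times, and 1 and 2 adjusted over the list alone). Among 6 WRKY factors, WRKY22 rose at all 3 times, by 2.32 ± 0.32, 2.09 ± 0.31 and 1.47 ± 0.32, and WRKY42 and WRKY6 rose at 1 d and 3 d. WRKY47 rose by 0.88 ± 0.22 at 3 d and WRKY53 stood at -1.36 ± 0.43 (called, but not without Col 3 d replicate 2, adjusted p = 0.118). WRKY6 was not called at 1 d within the larger spike-in set (adjusted p = 0.0544). Over the list 1, 3 and 4 rose and 0, 0 and 1 fell, with 1, 4 and 5 called adjusted over the list alone, and camera gave adjusted p of 0.0646, 0.0964 and 0.105 (0.195, 0.249 and 0.189 with an estimated correlation). The first became 0.0178 without dim probe sets, 0.016 with quantile normalization and 0.0489 with the spike-in set as a block, and it was also under 0.05 when any 1 of 5 arrays was left out (0.0267 to 0.0498). Of 6 senescence and autophagy genes, ATG8F, of autophagosome formation, stood at -0.32 ± 0.09 at 8 h (adjusted p = 0.0276), fell by 0.50 ± 0.08 at 1 d and fell by 0.56 ± 0.09 at 3 d, and ATG8E rose by 1.33 ± 0.24 at 3 d. The 8 h call of ATG8F was lost with median centring (0.0686), with the spike-in set as a block (0.0674), within the larger set (0.138), on the arrays compared alone (0.0598) and when any 1 of 6 arrays was left out (up to 0.114). That list had 0, 1 and 2 members risen and 1, 1 and 2 fallen (1, 2 and 4 called adjusted over the list alone; camera adjusted p = 0.634, 0.525 and 0.984), and its median, mean and test differed in sign at 8 h (-0.02, 0.01, down) and 3 d (-0.12, 0.06, up).

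Of 5 heat shock genes, HSP15.7 fell by 1.47 ± 0.36 at 1 d and fell by 1.37 ± 0.37 at 3 d. The list was not called (0, 1 and 1 fallen, the same counts adjusted over the list alone; camera adjusted p = 0.569, 0.457 and 0.346). Of 6 antioxidant genes, NDB2, an alternative NAD(P)H dehydrogenase of mitochondria, rose by 0.61 ± 0.13 at 1 d and stood at 0.46 ± 0.14 at 3 d, where its call was lost without Col 3 d replicate 2 (adjusted p = 0.065). With the replicate number as a block, an effect shared by all accessions, NDB2 was also called at 8 h (0.38, adjusted p = 0.0132). That list, with 0, 1 and 1 risen and 0, 0 and 1 fallen (the same counts adjusted over the list alone), was not called (camera adjusted p = 0.82, 0.925 and 0.681). At 1 d its median was -0.06 and its mean 0.07. The call of GR, its fallen member at 3 d, was lost when a certain 1 array was left out. The late embryogenesis list at 8 h, with 1 of 7 risen (2 adjusted over the list alone), had a median of -0.08 and a mean of -0.01 under a test that leaned up (adjusted p = 0.634). The flavonoid list at 8 h had 1 of 6 called (1 adjusted over the list alone), UGT78D1 at -0.62 ± 0.17, and camera gave an adjusted p of 0.14 (0.699 with an estimated correlation, and 0.0117 without Col cold acclimated replicate 3). The call of UGT78D1 was lost with quantile normalization (0.0698), with the spike-in set as a block (adjusted p = 0.0679), within the larger set (0.0799) and when any 1 of 7 arrays was left out (up to 0.0911). Among 4 auxin genes IAA29 stood at -0.38 ± 0.13 at 1 d (1 fallen, 2 adjusted over the list alone), a call lost with median centring (0.104), on the arrays compared alone (0.0999) and when any 1 of 10 arrays was left out (adjusted p up to 0.0851). GH3.3 stood at 0.92 ± 0.34, 0.45 ± 0.33 and 0.70 ± 0.34, not called. It was called at 8 h and 3 d with accession and replicate as a random block (adjusted p = 0.0315 and 0.0423) and without Col cold acclimated replicate 2 (0.0248 and 0.0171), and at 8 h without Col 8 h replicate 1 (0.0349). The only measured gene of the sugar list, the sucrose phosphate synthase SPS4F, stood at -0.24 ± 0.32, -0.61 ± 0.30 and -0.67 ± 0.32, not called over all genes (0, 0 and 1 adjusted over the list alone). With the replicate number as a block it was called at 1 d (-0.61, adjusted p = 0.0233) and 3 d (-0.77, 0.00496), and at 3 d also with array weights (0.0151) and with the spike-in set as a block (0.039). In the jasmonate list PDF1.2 stood at -0.97 ± 0.96, -0.24 ± 0.92 and -0.56 ± 0.96, and neither it nor THI2.1 was called (0 of 2 adjusted over the list alone).

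Markers of other cell types were few. The guard cell genes FAMA and GASA9 and the root hair genes EXPA7 and EXPA18 passed limma's test at no time, with 0 of 2 called adjusted over the list alone for both lists. GASA9 stood at 0.09 ± 0.48, 0.58 ± 0.46 and 0.52 ± 0.48, FAMA at 0.11 ± 0.10, -0.10 ± 0.09 and -0.11 ± 0.10, and EXPA7 at 0.17 ± 0.10, 0.00 ± 0.09 and -0.01 ± 0.10. Of 4 reference genes, GAPC2, of glycolysis, fell by 0.33 ± 0.07 at 1 d and fell by 0.52 ± 0.08 at 3 d (1, 1 and 1 fallen at the 3 times adjusted over the list alone, with 0, 0 and 2 risen). At 8 h GAPC2 was called only with the replicate number as a block, fixed (-0.23, adjusted p = 0.0214) or random within accession (0.0301), and without Rsch 8 h replicate 1 (0.0353). TIP41L, SAND and UBC21 were not called over all genes, with values between -0.09 and 0.28. The lists of abscisic acid, aquaporin, membrane lipid, floral and vascular genes had no member named on the array here and were not analysed here, nor were CBF1, CBF2 and CBF3.

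Within accessions, Col had 90 called probe sets at 8 h, 1861 at 1 d and 3592 at 3 d, Rsch had 297, 1406 and 2158, and Te had 72, 793 and 2975. The order of 1 d and 3 d turned in Col on the arrays compared alone (3, 529 and 132) and without 3 d replicate 2 (675 at 3 d). It turned in Rsch too, with 1078 at 3 d and more at 1 d on the arrays compared alone, and with 987 and 1015 at 3 d without 3 d replicates 2 and 3. Calls found in all 3 accessions in 1 direction were 31 higher and 0 lower at 8 h, 274 and 153 at 1 d, and 417 and 619 at 3 d, where 0 and 0, 0.6 and 0.4, and 2.8 and 9.7 would be shared by independent lists. The 3 lists are not independent, since they come from 1 fit with a spread per probe set common to all groups. The numbers for independent lists are therefore no test of sharing. Across probe sets, which are not independent replicates, the log2 fold changes of 2 accessions correlated at r = 0.63 to 0.83. AT5G62360 and XTH18 were called at each time in each accession, and AT3G59350 rose by 3.00 ± 0.47, 3.19 ± 0.42 and 2.18 ± 0.42 at 8 h in Col, Rsch and Te. AT1G30250 fell at 8 h in Col (-1.89 ± 0.34) and Rsch (-1.95 ± 0.31) and stood at -0.97 ± 0.31 in Te (limma adjusted p = 0.326). UGT78D1 fell at 3 d in each, with -2.64 ± 0.31, -1.53 ± 0.28 and -1.52 ± 0.28. Whether accessions differed in such changes was tested separately, as interactions.

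**Figure D4:**
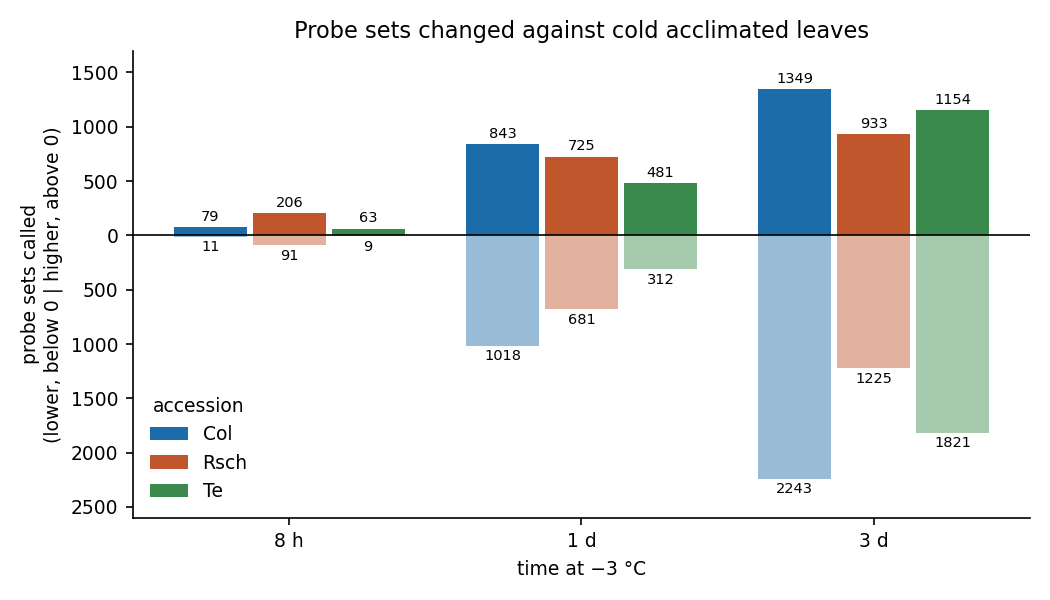
Number of probe sets called against cold acclimated leaves (y axis; higher drawn upward, lower downward) at 8 h, 1 d and 3 d within Col, Rsch and Te, with the counts printed at the bars. Col went from 79 higher and 11 lower at 8 h to 1349 higher and 2243 lower at 3 d.

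These counts moved with single arrays. The Col count at 8 h became 19 and 21 without 8 h replicates 1 and 2, and 58 without cold acclimated replicate 1. At 1 d it became 1213 without 1 d replicate 2 and 1162 without cold acclimated replicate 1. At 3 d it became 675 without 3 d replicate 2. The Rsch count at 8 h became 113 and 155 without cold acclimated replicates 1 and 2, and 134 without 8 h replicate 3. At 1 d it became 773 without cold acclimated replicate 1, and 835 and 670 without 1 d replicates 2 and 3. At 3 d it became 1054 and 1376 without cold acclimated replicates 1 and 3, and 987 and 1015 without 3 d replicates 2 and 3. The Te count at 8 h became 45 and 6 without cold acclimated replicates 2 and 3, and 18 and 10 without 8 h replicates 1 and 3. At 1 d it became 452 and 290 without cold acclimated replicates 2 and 3, and 396 and 307 without 1 d replicates 2 and 3. At 3 d it became 1492 without cold acclimated replicate 3, and 1314 and 1555 without 3 d replicates 2 and 3. With the spike-in set as a block the counts at 8 h, 1 d and 3 d were 87, 2330 and 4407 in Col, 255, 1779 and 2692 in Rsch and 49, 1086 and 3477 in Te. Within the larger set they were 96, 1008 and 2889 in Col, 171, 815 and 1677 in Rsch, and 84, 871 and 3072 in Te. With the replicate number as a block they were 2906 for Col at 1 d, 661, 2269 and 3496 for Rsch, and 119 and 1552 for Te at 8 h and 1 d. Median centring changed the split of higher and lower calls from 843 and 1018 to 1244 and 597 in Col at 1 d and from 1349 and 2243 to 2204 and 1525 in Col at 3 d. In Rsch it changed from 725 and 681 to 919 and 468 at 1 d and from 933 and 1225 to 1308 and 975 at 3 d, and in Te from 481 and 312 to 566 and 228 at 1 d and from 1154 and 1821 to 1644 and 1195 at 3 d. It moved the median of all probe sets by 0.12 and 0.13 in Col at 1 d and 3 d and by 0.11 in Te at 3 d.

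**Figure D5:**
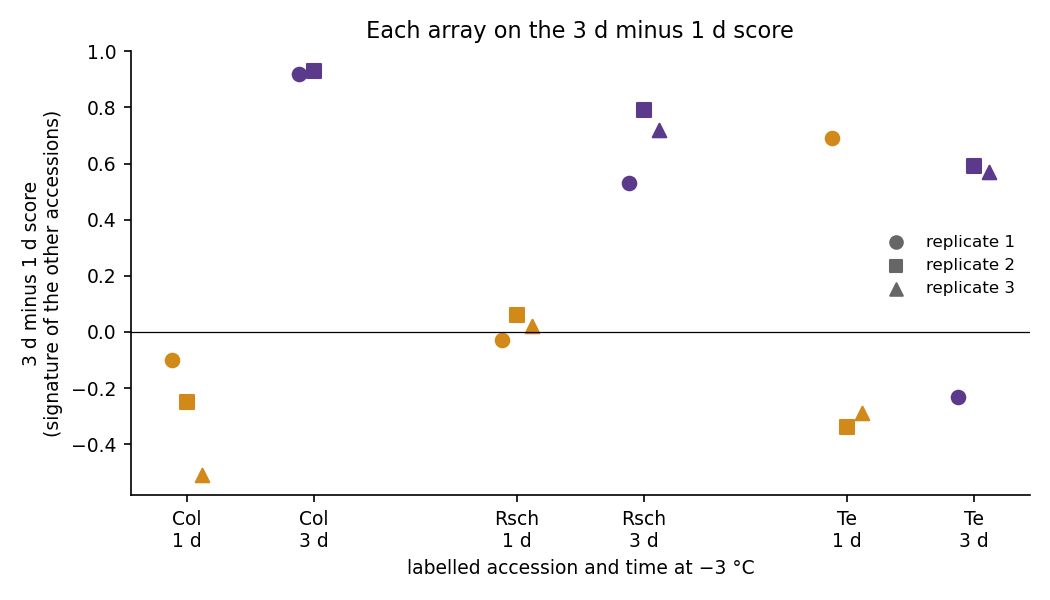
Score of each array at 1 d and 3 d (y axis) by accession and time (x axis), with the point shape giving the replicate. The score used the 500 probe sets that best separated 3 d from 1 d in the other accessions. Deviations from the mean of the array's own accession were weighted by the 3 d minus 1 d change there and summed. The sum was scaled to the size of that change, so it is not in log2 units and 3 d is high. The array labelled Te 1 d replicate 1 stands at 0.69 and the one labelled Te 3 d replicate 1 at -0.23.

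Of the 17 arrays at 1 d and 3 d, 2 lay nearer the other time on a score made from the other accessions. The array labelled Te 1 d replicate 1 scored 0.69, where the other two Te arrays at 1 d scored -0.34 and -0.29, and that labelled Te 3 d replicate 1 scored -0.23, where its partners scored 0.59 and 0.57. Col and Rsch arrays ranged from -0.51 to 0.06 at 1 d and from 0.53 to 0.93 at 3 d. The labels were kept as given. Without both arrays, a choice made after seeing the data, Te had 1017 calls at 1 d (77.8% of the 793 kept) and 3552 at 3 d (89.3% of the 2975 kept). GRX480 was then called at 1 d (1.37, adjusted p = 0.00692) and 3 d (-1.02, adjusted p = 0.035), and SPS4F at 3 d (-0.86, adjusted p = 0.023).

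Between 8 h and 1 d, AT2G38240 rose by a further 2.59 ± 0.39 (SE, 9 arrays against 8; limma adjusted p = 0.000228). AT4G28240, which had been low at 8 h, rose by 1.99 ± 0.37, AT3G43250 by 1.93 ± 0.44, AT1G51820 by 1.46 ± 0.26, XTH19 by 1.38 ± 0.29 and COR15B by 0.71 ± 0.16. AT4G27654 fell with a change of -2.66 ± 0.58, AT1G72240 with -1.73 ± 0.21, AT4G27657 with -1.63 ± 0.32 and UGT78D1 with -0.70 ± 0.17. AT4G22470 rose by 1.72 ± 0.38, with an adjusted p of 0.0502 without Col 8 h replicate 1. Limma called 1254 probe sets, 661 higher and 593 lower, against 803 and 443 after median centring. The count was 625 without Col 8 h replicate 1, 1929 with the replicate number as a block, 1886 with the spike-in set as a block (93% of the 1254 kept), 1235 within the larger set and 1301 without the 2 doubted Te arrays.

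Between 1 d and 3 d, AT1G19530 rose by 3.12 ± 0.55 (SE, 8 arrays against 9; limma adjusted p = 0.00733) and ATG8E by 1.19 ± 0.24, while AT2G42690 fell by 1.25 ± 0.26 and PRK fell by 1.06 ± 0.23. XTH33 rose by 2.19 ± 0.51, RCA fell by 0.51 ± 0.11 and MCCB fell by 0.55 ± 0.13, calls that were lost when any 1 of 3, of 1 and of 2 arrays was left out (adjusted p up to 0.0568, 0.057 and 0.073). Fitted on the 1 d and 3 d arrays alone, each of these genes but XTH33 had an adjusted p between 0.0503 and 0.062. Limma called 909 probe sets, 414 higher and 495 lower, and 2797 without the 2 doubted Te arrays, which kept 905 of the 909. The split turned to 494 higher and 460 lower with quantile normalization and to 488 and 458 with median centring. The count depended on single arrays and was 1908 without the array labelled Te 1 d replicate 1 and 2048 without that labelled Te 3 d replicate 1. It was 320 and 335 without Te 1 d replicates 2 and 3, and 230 and 318 without Te 3 d replicates 2 and 3. It was 495, 477 and 415 without Col 1 d replicate 3 and Col 3 d replicates 1 and 2, and 470, 581 and 552 without Rsch 1 d replicates 1 and 3 and Rsch 3 d replicate 3. It was 1828 with the replicate number as a block, 1292 with the spike-in set as a block, 1781 within the larger set, and 0 by limma within the smaller, which holds both doubted arrays (472 at an unadjusted p under 0.05).

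When cold acclimated, before any sub-zero treatment, Rsch and Col differed most in single genes with large steps. AT4G29200 was higher in Rsch by 6.08 ± 0.15 (SE, 3 arrays against 3; limma adjusted p = 4.9e-20), AT3G47320 by 4.73 ± 0.32, AT2G15560 by 4.42 ± 0.23, AT2G12050 by 3.83 ± 0.22 and AT5G41660 by 3.72 ± 0.15. Lower in Rsch were AT2G25510 at -7.58 ± 0.32, AT3G47250 at -6.59 ± 0.12, AT1G76960 at -6.44 ± 0.19, AT2G01090 at -5.42 ± 0.19 and AT5G45500 at -5.33 ± 0.20. AT2G25450, a dioxygenase of glucosinolate side-chain modification, stood at -5.85 ± 0.54. The probes follow the Columbia-0 sequence, so a sequence difference under a probe set would also lower its signal in Rsch or Te. Of the lists, CBF and COR genes were higher in Rsch (camera adjusted p = 0.006; adjusted p = 0.297 with an estimated correlation), with 1 of 7 called (5 adjusted over the list alone), COR47 at 0.90 ± 0.25. So were late embryogenesis abundant genes (adjusted p = 0.0177; adjusted p = 0.253 with an estimated correlation) with 1 of 7 called (2 adjusted over the list alone), again COR47. The 2 lists share COR47, COR15B and LTI30, so they are not independent. Both list calls were lost without Col cold acclimated replicate 3 (adjusted p = 0.228) and on the arrays compared alone (0.0881 and 0.0777), and the second also without dim probe sets (0.0651) and with array weights (0.0826). The call of COR47 was lost without Col cold acclimated replicate 3 (0.195), without Rsch cold acclimated replicate 1 (0.217), on the arrays compared alone (0.427), with array weights (0.0715) and within the larger spike-in set (0.153). Photosynthesis genes leaned up (adjusted p = 0.0621; adjusted p = 0.599 with an estimated correlation), and were called with median centring (0.0414), with array weights (0.00631), without the 2 doubted Te arrays (0.0332) and when any 1 of 5 arrays was left out (0.000536 to 0.045). Flavonoid genes, not called either (0.384; 0.652 with an estimated correlation), leaned down and were called with array weights (0.0275) and without Col cold acclimated replicate 3 (0.0102). PME41 at -2.63 ± 0.61 and UGT78D1 at -1.08 ± 0.28 were called, but not without any 1 of 3 and any 1 of 4 arrays (adjusted p up to 0.0723 and 0.0945), nor PME41 on the arrays compared alone (0.194) or within the larger set (0.108). Limma called 1115 probe sets, 479 higher and 636 lower in Rsch, of which 170 were at least 2-fold higher and 380 at least 2-fold lower. The count was 601 without Rsch cold acclimated replicate 1, 1824 with the replicate number as a block, 1345 with the spike-in set as a block and 430 within the larger set.

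Te also differed from Col by large steps. AT2G15130 was higher in Te by 7.49 ± 0.14 (SE, 3 arrays against 3), AT2G15560 by 4.91 ± 0.23, AT5G24240 by 3.78 ± 0.20 and AT1G50290 by 3.13 ± 0.30. Lower in Te were AT1G76960 at -6.66 ± 0.19, AT3G47250 at -6.46 ± 0.12, AT5G45500 at -5.34 ± 0.20 and AT3G22240 at -4.73 ± 0.18. The AT3G47250 probe set was dim in Te as well, with an average of 3.21, so the size of its difference is uncertain. ECS1, a cell wall protein gene, stood at -5.61 ± 0.20, and AT1G63880, of the TIR-NBS-LRR resistance genes, at -4.80 ± 0.22. Against Rsch, Te was higher in AT2G25510 by 7.50 ± 0.32, AT2G15130 by 7.35 ± 0.14, AT4G32240 by 5.97 ± 0.21, AT2G25450 by 5.28 ± 0.54, AT5G03350 by 4.98 ± 0.51 and QQS, a gene that affects starch content, by 4.86 ± 0.30. It was lower in AT4G29200 at -5.65 ± 0.15, AT3G47320 at -4.66 ± 0.32, ECS1 at -3.58 ± 0.20, AT4G12490 at -3.51 ± 0.37 and AT5G41660 at -3.45 ± 0.15. Of the list members, COR15B at -1.17 ± 0.27, XTH33 at 3.07 ± 0.86 and IAA29 at -0.95 ± 0.23 were called between Te and Rsch, but not without any 1 of 3, of 4 and of 3 arrays (adjusted p up to 0.0827, 0.234 and 0.184), on the arrays compared alone (0.0653, 0.167 and 0.297) or within the larger spike-in set (0.0506, 0.459 and 0.212). No list was called in either contrast, but some were under other settings. Photosynthesis genes leaned down in Te against Rsch (camera adjusted p = 0.0641; adjusted p = 0.448 with an estimated correlation) and were called on the arrays compared alone (0.000317), with array weights (0.0319), without the 2 doubted Te arrays (0.0378) and when any 1 of 5 arrays was left out (0.0139 to 0.0466). Flavonoid genes there, leaning up (0.178; 0.644 with an estimated correlation), were called on the arrays compared alone (0.0223). CBF and COR genes, leaning down (0.124; 0.448 with an estimated correlation), were called when any 1 of 3 arrays was left out (0.0256 to 0.0451), and heat shock genes, leaning up (0.124; 0.448 with an estimated correlation), without Te cold acclimated replicate 1 (0.0212). Between Te and Col, CBF and COR genes (up, 0.376) and dark and sugar starvation genes (down, 0.207) were called without Col cold acclimated replicate 1 (0.0407 for both; 0.737 and 0.656 on all arrays with an estimated correlation). Median and test differed in sign for photosynthesis genes between Te and Col (0.02, down). Median and mean did so for cell wall enzymes between Te and Rsch (-0.01, 0.30) and, between Te and Col, for senescence genes (0.16, -0.07) and WRKY factors (0.04, -0.03). Limma called 1251 probe sets between Te and Col, 601 higher and 650 lower in Te, and 814 between Te and Rsch, 431 higher and 383 lower. The split between Te and Rsch turned to 407 higher and 420 lower with quantile normalization and to 389 and 405 with median centring. The first count was 695 without Te cold acclimated replicate 3, 1467 with the spike-in set as a block and 996 within the larger set. The second was 542 without Rsch cold acclimated replicate 1, 541 and 470 without Te cold acclimated replicates 2 and 3, 949 with the block and 497 within the larger set.

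The change from the cold acclimated state was tested for a difference between the accessions with a moderated F test. At 8 h 1 probe set passed, that of AT1G57850, a TIR domain gene (limma adjusted p = 0.00347), with changes of 2.44 in Col, 2.21 in Rsch and 0.21 in Te. At 1 d 6 passed, 5 of them with 1 gene each. AT2G34910 changed by 1.43 in Col, 0.13 in Rsch and 0.15 in Te (adjusted p = 0.00216), and AT3G47250 by -0.88, 0.15 and 0.14 (0.00767). The AT3G47250 probe set had no group mean above 3.23 in Rsch and 3.35 in Te, against 9.67 in cold acclimated Col, so no decrease like that of Col can be seen there and this call does not speak of a different response. The pseudogene AT5G28430 changed by 3.95, -0.91 and 2.35 (0.00899), AT1G28375 by 0.95, 0.14 and 0.02 (0.00899), and AT1G57850 by 2.1, 1.81 and 0.38 (0.0463). At 3 d 7 passed, 2 of them with 1 gene, AT3G46280 at 4.1, 3.63 and 0.62 (0.0288) and AT5G28430 at 2.83, -1.17 and 2.48 (0.0483). The calls of AT1G57850 at 1 d and of both genes at 3 d were lost when any 1 of 14, of 9 and of 15 arrays was left out (adjusted p up to 0.256, 0.104 and 0.195) and without the 2 doubted Te arrays (0.172, 0.0952 and 0.0655). That of AT1G57850 at 1 d was also lost with the replicate number as a block. AT1G28375 and AT5G28430 at 1 d lost theirs without any 1 of 2 arrays (up to 0.0689 and 0.0707). Fitted on the arrays compared alone, each gene named at 1 d had an adjusted p between 0.0778 and 0.182 and those at 3 d had 0.108. Within the larger spike-in set each but AT2G34910 lost its call at 1 d (0.116 to 0.733), and so did both at 3 d (0.191 and 0.148). The 3 d count was 0 by limma without Col 3 d replicate 2 (755 at an unadjusted p under 0.05), 23 without Col 3 d replicate 1, 2 and 3 without Te 3 d replicates 2 and 3, and 4 without Te 3 d replicate 1, Rsch cold acclimated replicate 3 or any 1 Te cold acclimated array. The 8 h count was 2 without Col 8 h replicate 2. With the spike-in set as a block the counts were 1, 6 and 10, and within the larger set they were 1, 3 and 9. At an unadjusted p under 0.05 the counts were 353, 523 and 852.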

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

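The tests of the array labels, RNA quality and mixed RNA in the 2 Te arrays, that of the at least 2-fold changes between accessions, the regroupings that part every pair, and the fits with the spike-in set or without the 2 Te arrays were chosen after the results were seen.

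Accessions differed in their change from the cold acclimated state at 1 probe set at 8 h, 6 at 1 d and 7 at 3 d, by a test of the difference itself. The genes were AT1G57850 at 8 h (adjusted p = 0.00347), AT2G34910 (0.00216), AT3G47250 (0.00767), AT5G28430 (0.00899), AT1G28375 (0.00899) and AT1G57850 (0.0463) at 1 d, and AT3G46280 (0.0288) and AT5G28430 (0.0483) at 3 d. Regrouping the arrays left chance open at 8 h, where 15 of 100 regroupings called as many (1, against 14 in the highest other), and at 3 d, where 5 of 100 did (7, against 10). At 1 d 2 of 100 called as many, the real one included (6, against 6 in the highest other), a share under 0.05. This was 1 of 3 such tests, and another regrouping reached the same count. On the arrays compared alone limma called 0 at 1 d (552 at an unadjusted p under 0.05). Chance was therefore not excluded at 1 d either. Without the 2 doubted Te arrays 5 probe sets passed at 1 d, all among the 6, and 6 at 3 d, 4 of them among the 7. The AT3G47250 probe set had group means of at most 3.23 and 3.35 in Rsch and Te, against 9.67 in cold acclimated Col, so its call follows from the missing signal and says nothing of a different response. AT1G57850 and AT3G46280 stayed below the 5.32 that marks dim probe sets in Te (at most 4.01 and 4.59), so probes that miss the transcript there stay open. AT2G34910 and AT1G28375 stayed below it in all 3 accessions (at most 5.09 and 4.66, in Col), and leaving out dim probe sets removes both. No biological explanation of the other differences was tested. Groups had at most 3 arrays, so single arrays were not tested for their distance from their group.

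The arrays labelled Te 1 d replicate 1 and Te 3 d replicate 1 lay nearer each other's time than their own. Lower RNA quality was argued against, since all 4 Col and Rsch arrays with an actin difference above every replicate 2 or 3 array at these times lay nearer their own time, although these had 1.81 to 2.49 and both Te arrays, with 2.51 and 2.55, lay just above them. A mixture of both RNAs was argued against too, since it would put both arrays near the midpoint of 0.13 between the Te times, and they stood at 0.69 and -0.23. Exchanged labels remain a candidate explanation, with a score of 0.69 where the other two Te arrays at 1 d had -0.34 and -0.29, and a second score, from 8 h against cold acclimated leaves, of -0.28 (partners 0.41 and 0.28) and 0.37 (partners -0.07 and -0.09) that was also crossed, as was Rsch 3 d replicate 2 (0.07), an array not doubted, so this second score parts the times less well. A true difference of these leaf pools stays open and untested, and leaving out both arrays moved the 3 d against 1 d count from 909 to 2797.

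The changes against cold acclimated leaves were large at every time, and temperature, detachment and darkness go together in this design. The hour of day at sampling entered no fit, so whether time of day had a part in these changes was not tested. Of the 25 sub-zero arrays 16 lay within the actin range of the cold acclimated ones. An overlap of ranges cannot exclude differing RNA quality, and no fit adjusted for the actin difference. Its averages were 1.74 log2 when cold acclimated, 1.44 at 8 h, 1.65 at 1 d and 1.86 at 3 d. RNA quality therefore stays open as a part of the cause. The split of the arrays by bioC level was argued against as the whole cause, since 67% of the 8 h calls were kept with it as a block. Other cell types cannot be told apart, since no list of their markers held more than 2 measured genes. Darkness and detachment cannot be told apart from cold either. Dark and sugar starvation genes had medians of -0.39, -0.48 and -0.18 at 8 h, 1 d and 3 d, where carbon-starved leaves would raise them. Only 5 of them were measured, and their mean plus 2 SE reached 0.04 at 3 d. The prediction written beforehand also had light-harvesting genes fall in darkness. The photosynthesis list, which holds LHCB4.2, went that way, with medians of -0.36, -0.41 and -0.98. An effect of the sub-zero temperature itself stays open as a hypothesis.

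When cold acclimated, probe sets lower than in Col outnumbered the higher ones, above all among large differences. Of all calls, shares of 0.57 in Rsch and 0.52 in Te were lower, which leaves sequence differences from the Columbia-0 probes open, with 0.471 between Te and Rsch. Of calls of at least 2-fold the shares were 0.691 and 0.674, against 0.487 between Te and Rsch, as sequence differences under the probes would give. Such differences may contribute to the large decreases, but the share of 0.674 or more counts lower calls among all such calls and not the decreases that they explain. True losses of expression stay open, and no probe sequence was used here.

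Regroupings of the arrays within each accession called as many in 1 of 100 for each averaged count, the real one: 1352 at 8 h (highest other 47), 5729 at 1 d (2768), 8403 at 3 d (6298), 1254 from 8 h to 1 d (184) and 909 from 1 d to 3 d (732). Most of these put arrays of equal replicate number, which vary together, into 1 group, so 100 regroupings were drawn among those that part every such pair, as the real one does. They called as many in 1 of 100, the real one, at 8 h (highest other 721), 1 d (3842) and 3 d (6298) and from 8 h to 1 d (581), which excluded chance at a share under 0.05. These highest others lay close to the real grouping or to its mirror. They exchanged 1 pair at 1 d and at 3 d, 7 of 8 pairs at 8 h and all 8 from 8 h to 1 d. From 1 d to 3 d 4 of 100 called as many (highest other 3170), also a share under 0.05. The highest there was the exchange of the 2 doubted Te arrays alone. A count over 3 times that of the given labels points to a structure of these arrays, weighed above. Within accessions and between them the 10 splits were too few for a share under 0.05, with 1 of 10 as large in each. The real and highest other counts were 1861 and 148 for Col at 1 d, 297 and 0, 1406 and 0, and 2158 and 0 for Rsch at 8 h, 1 d and 3 d, and 72 and 46, 793 and 1, and 2975 and 3 for Te. Between accessions they were 1115 and 136 for Rsch against Col, 1251 and 42 for Te against Col, and 814 and 54 for Te against Rsch. Groups of Col at 8 h and 3 d had 2 arrays and were not regrouped.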

How the results depend on the processing

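The fits with the spike-in set as a block or within a set, and without both doubted Te arrays, were chosen after the data were seen, and the others were planned. No call of a named gene or list was reversed under any setting. Over the settings other than leaving out 1 array, gene results kept their side of the threshold in 2892 cases, lost a call in 151 and gained one in 23, and list results did so in 670, 33 and 11. With 1 array left out these numbers were 3233, 214 and 13 for genes and 2006, 11 and 23 for lists. Where no cause is given, the cause was not tested. Dim probe sets were judged by their level alone. Where a left-out array left a group with 1, that array was assumed to vary like the other groups. Array weights, trend and the random block changed the spread and not the set of arrays, and trend and the random block do not apply to the list tests.

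Counts that moved by over 1.5 times are given by setting. Without dim probe sets, and without probe sets of suffix _s_at or _x_at, the interaction at 1 d had 3, and fewer probe sets were tested there. With array weights the counts were 2083 for the averaged 8 h contrast, 2109 from 8 h to 1 d and 2409 from 1 d to 3 d, 218 and 2350 for Col at 8 h and 3 d, 462, 2644 and 3331 for Rsch at 8 h, 1 d and 3 d, 139, 1676 and 5680 for Te, 1802 for Rsch against Col, 2032 for Te against Col and 12 for the interaction at 3 d; the cause was not tested.

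With the replicate number as a block the counts were 2245 for the averaged 8 h contrast, 1929 from 8 h to 1 d and 1828 from 1 d to 3 d, 148 and 2906 for Col at 8 h and 1 d, 661, 2269 and 3496 for Rsch, 119 and 1552 for Te at 8 h and 1 d, 1824 for Rsch against Col and 1932 for Te against Col. The pairing could not be judged for Col at 8 h, with 2 pairs, and did not hold for Te against Col. From 1 d to 3 d it held in Rsch (0.45 to 0.55), had 2 pairs in Col (0.41 and 0.49) and failed in Te (-0.24 to 0.01), which holds the 2 doubted arrays. The block changed no list call. It gained 7 gene calls, NDB2 (adjusted p = 0.0132) and GAPC2 (0.0214) at 8 h, SPS4F at 1 d (0.0233), at 3 d (0.00496) and in Rsch against Col (0.0142), and AKINBETA1 (0.0329) and HSP15.7 (0.029) in Te against Col, which the numbers do not pair. It lost 1, that of AT1G57850 in the interaction at 1 d (adjusted p = 0.0518), and kept between 99.3% and 100% of the calls of each count other than the interactions. With accession and replicate as a random block (correlation 0.26) the counts were 2741, 2400 and 2310 for the averaged 8 h, 8 h to 1 d and 1 d to 3 d contrasts, 178 and 3317 for Col at 8 h and 1 d, 863, 2492 and 4081 for Rsch, 184, 1898 and 4734 for Te, and 3, 10 and 34 for the interactions.

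Fitted on the arrays compared alone, with fewer arrays for the spread, Col had 3, 529 and 132, Rsch 19 at 8 h and 1078 at 3 d, Te 347 at 1 d, and 1 d to 3 d 68. Rsch against Col, Te against Col and Te against Rsch had 292, 318 and 403, and the interactions 2, 0 by limma (552 at an unadjusted p under 0.05) and 2. With the correlation between genes estimated, camera called 0 of the 18 lists called otherwise (8 at an unadjusted p under 0.05 among 60). With the spike-in set as a block 8 h to 1 d had 1886. Within the larger set, with fewer arrays, the counts were 1008 for Col at 1 d, 171 and 815 for Rsch at 8 h and 1 d, 1781 for 1 d to 3 d, 430 for Rsch against Col, 497 for Te against Rsch and 3 for the interaction at 1 d. Within the smaller set, of 9 arrays, they were 441 at 1 d, 755 at 3 d and 0 by limma for 1 d to 3 d (472 at an unadjusted p under 0.05). Without both doubted Te arrays 1 d to 3 d had 2797.

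With 1 array left out the counts ranged from 726 to 1543 at 8 h, 4897 to 5826 at 1 d, 6578 to 8685 at 3 d, 625 to 1625 from 8 h to 1 d and 230 to 2048 from 1 d to 3 d. For 8 h, 1 d and 3 d they ranged from 19 to 125, 1162 to 1829 and 675 to 3467 in Col, 113 to 314, 670 to 1071 and 987 to 2515 in Rsch, and 6 to 61, 290 to 930 and 1314 to 3409 in Te. The ranges were 601 to 1080 for Rsch against Col, 695 to 1328 for Te against Col, 470 to 722 for Te against Rsch, 1 to 2, 4 to 8 and 0 to 23 for the interactions (755 at an unadjusted p under 0.05 by limma where it was 0), and 17 to 20 for the lists called. The mean of all probe sets of a gene, trend and robust settings, quantile normalization and median centring moved none of these counts by over 1.5 times.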

Other observations

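The tests of gene families by symbol stem and of organelle-encoded genes were chosen after the annotation had been seen, the genes named here were chosen after their values were seen, and the settings over which they were followed were in part chosen after the data were seen.

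Among 16 measured mitochondrion-encoded genes, cox1, a subunit gene of cytochrome c oxidase, rose at all 3 times. Its log2 changes, averaged over accessions, were 1.28 ± 0.16 at 8 h (SE, 8 arrays against 9; limma adjusted p = 9.88e-06), 1.49 ± 0.15 at 1 d and 1.72 ± 0.16 at 3 d (adjusted p = 2.62e-08), and these calls held in all 40 settings tried. The complex I gene nad6 rose by 0.46 ± 0.13, 0.59 ± 0.13 and 0.87 ± 0.13, although its call at 8 h was lost in 14 of 40 settings (adjusted p up to 0.134, without Col 8 h replicate 1). As a group the mitochondrial genes shifted up at 8 h (camera adjusted p = 0.0072 over 38 families; adjusted p = 0.6 with an estimated correlation), with 2 risen, 0 fallen and a median of 0.18, and the call was lost without Rsch cold acclimated replicate 2 (0.0509). They were not called at 1 d or 3 d (0.127 and 0.129). When cold acclimated, they were higher in Te than in Col (median 0.33; adjusted p = 0.00133; adjusted p = 0.533 with an estimated correlation) and than in Rsch (median 0.34; adjusted p = 0.0011; adjusted p = 0.69 with an estimated correlation), with cox2 higher in Te by 1.33 ± 0.20 and 1.03 ± 0.20. The first of these calls was lost without Col cold acclimated replicate 2 (0.0524). The 69 chloroplast-encoded genes were higher in Te than in Col when cold acclimated (median 0.69, 6 called; adjusted p = 6.44e-06; adjusted p = 0.844 with an estimated correlation), and rps4, of the small ribosomal subunit, was higher by 1.96 ± 0.27. They were also higher in Rsch than in Col (median 0.43, 1 called; adjusted p = 0.00117; adjusted p = 0.848 with an estimated correlation), but not within the larger spike-in set (median 0.24, 0.448) or when any 1 of 3 arrays was left out (up to 0.396). At no time did they shift against cold acclimated leaves (0.905, 0.901 and 0.45). The directions of these calls were the same under quantile normalization and median centring. Whether the RNA amplification captured organelle-encoded transcripts as it did nuclear ones was not tested. The values for these genes therefore describe array signal, which need not follow transcript amount.

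The 9 measured XTH genes, 6 of which are also in the cell wall list, shifted up at 1 d (median 0.54; camera adjusted p = 0.00372; adjusted p = 0.0319 with an estimated correlation) and 3 d (median 0.69; adjusted p = 0.00274; adjusted p = 0.0268 with an estimated correlation), with 5 risen and 1 fallen at both times. These calls held in each scaling, in the larger spike-in set (0.0172 and 0.0126) and with each array left out. At 8 h the camera adjusted p was 0.0542, and 0.0352 with the spike-in set as a block. The member that fell was XTH32, at -0.88 ± 0.27 and -1.18 ± 0.28. Of 20 beta-glucosidase (BGLU) genes 6 rose and 0 fell at 1 d (median 0.20; adjusted p = 0.0306; adjusted p = 0.126 with an estimated correlation), a call lost with quantile normalization (0.0581) and when any 1 of 2 arrays was left out (up to 0.0595). At 3 d 6 rose as well (adjusted p = 0.0743). BGLU15 rose by 1.63 ± 0.26 at 1 d and 2.18 ± 0.27 at 3 d, and BGLU25 by 0.64 ± 0.14 and 1.01 ± 0.14. At 8 h 8 autophagy (ATG) genes shifted down (median -0.28; adjusted p = 0.0297; adjusted p = 0.6 with an estimated correlation). The 1 member that fell, ATG8F, lost its call when any 1 of 6 arrays was left out (adjusted p up to 0.114).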
